A study of Drosophila melanogaster with 24 samples.

How the data were processed

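Fat bodies were dissected from Drosophila melanogaster larvae, and total RNA was extracted with a silica column kit and sequenced as 150 bp read pairs, per the labels' protocols. The labels give the genotype and the day after egg laying of each of the 24 samples, which form 6 groups of 4 libraries: tumour-bearing larvae at days 4, 5, 8 and 11 and control larvae at days 4 and 5. Eggs were collected over 3 hours and each sample pooled the fat bodies of 50 larvae, per the labels. The authors deposited whole-number counts of reads per gene and library, without normalization, for 17698 gene identifiers. STAR 2.5.4a and the genome build BDGP6 are named, without a stated role, per the submitters' processing notes. The counting program, the annotation release and the use of strand are not given in the sources used here. Reads of near-identical copies (AttA and AttB, the Hsp70 genes, the Lsp1 genes, Sgs7 and Sgs8, Amy-p and Amy-d) and of overlapping or antisense genes can therefore be split in ways that the counts do not show, and values of such genes are uncertain.

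Gene symbols were looked up by identifier for 17560 of the 17698 genes, and 138 had none. Coordinates are those of the BDGP6.54 annotation for the same identifiers. All statistics were computed from the deposited counts in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, with DESeq2 1.42.0 as an alternative, and in Python 3.11.15. Genes with low counts were removed with filterByExpr on the 6 groups, which left 8707 genes, and libraries were scaled by TMM. Before testing, libraries of 1 group were compared in pairs. They differed by a chi-square over degrees of freedom of 9.54 to 238, so no library was a copy of another. The first 2 principal components held 35.6% and 26.7% of the variance. The biological coefficient of variation was 0.284.

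Differential expression was tested with edgeR's quasi-likelihood test (robust) in 1 model with a mean for each of the 6 groups over all 24 libraries. The 9 contrasts were tumour against control at days 4 and 5, the difference between these, day 5 against day 4 in controls and with tumours, days 8 against 5 and 11 against 8 with tumours, and tumour days 8 and 11 against control day 5. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the test's F statistic. The design, the 40 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except those named as later additions. Of the list entries 755 matched a gene, 10 did not and 1 was a duplicate. Each list was tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, and its members were also counted after adjustment over the list alone. Named genes were the 8 highest and 8 lowest log2 fold changes among called genes with at least 20 CPM in the higher group and no overlap between the libraries of both groups (5 each for tumour day 11 against control day 5 and, without the last condition, for the difference). Up to 4 called members of each list described were added, and 11 genes were named in every case: scrib, ImpL2, upd3, Ilp8, Thor, Lsp2, Fbp1, Kr-h1, Eip93F, bmm and FASN1. Where those genes had 1 to 3 counts in the lower group, the ratio of summed counts is given with an exact binomial 95% interval, which covers counting error only.

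Total counts ranged from 16074877 to 23352151 per library and 9424 to 12427 genes had at least 1 count. Tested on simulated counts for the real genes, the day 4 comparison recovered 40.3%, 71.6% and 92.4% of genes changed 1.5, 2 and 4-fold among 8576 tested, with 8 of 8356 unchanged genes called, and the day 5 comparison 41.8%, 68.7% and 89.4% among 8559, with 7 of 8339. For control day 5 against day 4 the shares were 40.3%, 71.6% and 89.4% among 8549 (4 of 8329 unchanged genes called), for tumour day 8 against day 5 46.3%, 74.6% and 93.9% among 8512 (13 of 8292), and for day 11 against day 8 43.3%, 71.6% and 86.4% among 8546 (11 of 8326). In each simulation the shifted list was called and none of 38 unshifted lists was. The simulated genes varied independently, so these runs do not test camera's preset correlation on genes that vary together. Each run changed only 67, 67 and 66 genes by 1.5, 2 and 4-fold, besides the shifted list. The real comparisons of days 4 and 5 called 2191 and 4778 of 8707 genes. Recovery and false calls can depend on the share of changed genes, so these figures hold for the simulated setting only. Alternatives were RLE scaling, DESeq2, no low-count filter, only the groups compared in the model, scaling without the 20 most abundant genes, a replicate block, dispersion without the robust option, a minimum of 2-fold, each library left out in turn, an estimated correlation or ranks in camera, and 2 settings, 1 without 2 day 5 tumour libraries with gut or testis RNA and 1 without the 2 control libraries with the most salivary gland RNA, which were chosen after the data were seen. No library was left out of the results given first.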

Results

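RNA was sequenced from the larval fat body of Drosophila melanogaster, the organ that stores fat and glycogen and secretes storage proteins and antimicrobial peptides. In the tumour groups, C855a-Gal4, a driver active in epithelia, expressed a hairpin RNA against scrib, a cell polarity gene whose loss turns the wing discs into tumours. In the control groups it expressed a control hairpin. Tumour-bearing larvae were sampled 4, 5, 8 and 11 days after egg laying and control larvae at 4 and 5 days, with 4 libraries in each of the 6 groups and the fat bodies of 50 larvae in each library. Tumour-bearing larvae do not pupate, per the labels, and no control of day 8 or 11 is used here. Total counts ranged from 16074877 to 23352151 per library, and 8707 of 17698 genes passed the low-count filter. Levels below are CPM, read counts scaled to library size with TMM factors, as mean ± SD of 4 libraries. Changes are log2 fold changes ± SE from edgeR's quasi-likelihood test, with genes called at a Benjamini-Hochberg adjusted p under 0.05. The labels do not say that the 4 pools of a group came from separate cultures, so p-values measure only the spread between these pools.

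The knocked-down gene, scrib (FBgn0263289; chromosome 3R, 26536350 to 26604051, BDGP6.54 annotation), was read in every library first. Its CPM was 39.5, 42.2, 42.4 and 35.3 in the 4 control libraries of day 4 and 33.7, 39.0, 27.9 and 35.6 in the 4 tumour libraries of that day. At day 5 it was 43.4, 48.4, 41.4 and 43.2 in controls and 38.3, 34.4, 34.1 and 35.6 with tumours, a called difference of -0.31 ± 0.10 on the log2 scale (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.01). The day 8 libraries held 32.0, 35.7, 41.8 and 35.4 CPM and the day 11 libraries 38.8, 40.7, 45.4 and 44.3 CPM. Since the driver is an epithelial one and the fat body was sampled, these values do not check the labels. The day 5 call ended without replicate 3 of tumour day 5 (-0.24, adjusted p = 0.0833). At day 4 scrib was called lower only without replicate 2 of tumour day 4 (-0.30, adjusted p = 0.0346; -0.23 with all 8 libraries, adjusted p = 0.092).

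The first comparison asked how fat body transcripts differed between tumour-bearing and control larvae at day 4. Fbp1 (FBgn0000639; 3L, 14094589 to 14098053), a receptor for storage proteins, was at 363 ± 168 CPM with tumours and 44667 ± 31414 in controls, a log2 fold change of -6.94 ± 0.76. Oat, ornithine aminotransferase (3L, 19647280 to 19649851), fell from 680 ± 461 to 6.48 ± 3.69 CPM (-6.70 ± 0.54). In the other direction Cyp12a4, a cytochrome P450 (3R, 19135158 to 19137136), was at 99.9 ± 33.0 CPM against 2.86 ± 0.83 (5.12 ± 0.27). The glucosidase gene tobi, known as a target of brain insulin (3R, 25344761 to 25346921), was at 396 ± 107 against 28.1 ± 4.63 (3.82 ± 0.50). Among the 16 genes with the largest changes under the naming rule were also Jon74E (3.89 ± 0.34), MFS12 (3.58 ± 0.26), CG16898 (3.41 ± 0.49), Nepl11 (3.63 ± 0.53), CG16762 (4.04 ± 1.12) and CDase, a ceramidase (3.42 ± 0.37), all higher with tumours. The gene FBgn0259822 was lower (-7.44 ± 0.64). In all, 2191 genes were called, 1274 higher and 917 lower, and 713 of them differed at least 2-fold. Without replicate 2 of control day 4 the changes of CG16898 and Nepl11 were 4.05 and 4.57, and without replicate 1 of tumour day 4 that of CG16762 was 3.25.

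Transcripts of energy metabolism and of the ribosome were higher with tumours at day 4. Of 46 oxidative phosphorylation genes 45 rose (45 adjusted over the list alone), with a median log2 fold change of 0.60 and COX5B at 0.73 ± 0.15 and ATPsynbeta at 0.71 ± 0.15. The ribosomal protein list rose in 76 of 79 members (79 adjusted over the list alone), with a median of 0.42. In the tricarboxylic acid cycle 12 of 15 genes rose (12 over the list alone), with SdhA at 1.08 ± 0.15. Of 13 glycolysis genes 8 rose (11 adjusted over the list alone), with Hex-A at 1.21 ± 0.13. Of 13 genes of glycogen and trehalose metabolism 8 rose and 2 fell, with glycogenin, Gyg, at 1.92 ± 0.25. Of 18 genes of fatty acid and triacylglycerol synthesis 8 rose and 2 fell, with Men, malic enzyme, at 1.5 ± 0.17, Gpdh1 at 1.73 ± 0.26 and Desat1 at 1.36 ± 0.22. Both counts were the same adjusted over the list alone. These 6 lists were called by camera, which compares a list with all other genes. Its adjusted p was 9.57e-15 for oxidative phosphorylation, 1.6e-20 for ribosomal proteins, 1.73e-05 for the tricarboxylic acid cycle, 0.000206 for glycolysis, 0.000323 for glycogen and trehalose and 0.00566 for fatty acid synthesis. None was called with an estimated correlation between genes, where adjusted p = 0.752, 0.752, 0.34, 0.482, 0.318 and 0.752 with an estimated correlation, in the same order. Glycogen and trehalose metabolism was not called by camera's rank test either (adjusted p = 0.0576).

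Single genes of other lists also differed at day 4. ImpL2 (3L, 4224006 to 4236147), which encodes a binding protein of insulin-like peptides, was at 233 ± 17.8 CPM with tumours and 114 ± 22.5 in controls (1.03 ± 0.16). Thor, the 4E-BP translation repressor, was at 264 ± 106 against 127 ± 44.3 (1.06 ± 0.27), while Ilp6 fell (-0.73 ± 0.21). TotC, a secreted stress protein, rose 1.91 ± 0.29, and Tsf1, an iron transporter, rose 1.63 ± 0.28. FASN1 (0.23 ± 0.23), bmm (0.38 ± 0.17), Kr-h1 (-0.59 ± 0.28) and Eip93F (-0.09 ± 0.84) did not pass the test. Lsp2 fell (-0.80 ± 0.16). Kr-h1 passed it without replicate 2 of control day 4 (-0.84, adjusted p = 0.0085) or replicate 1 of tumour day 4 (-0.83, adjusted p = 0.0401), and without both controls with the most salivary gland RNA (-0.84, adjusted p = 0.00983). So did bmm without replicate 1 of either group (0.52 and 0.51, adjusted p = 0.0255 and 0.0456). With only the 8 libraries of day 4 in the model, Thor (adjusted p = 0.11), Ilp6 (adjusted p = 0.137) and Lsp2 (adjusted p = 0.0551) did not pass. Of 11 genes of the juvenile hormone response list, which holds Kr-h1, 4 rose and none fell at day 4 (4 adjusted over the list alone; median 0.28). These were Jheh1 (1.17 ± 0.11), Jheh2 (0.85 ± 0.16) and Jheh3 (0.67 ± 0.13), epoxide hydrolases of juvenile hormone breakdown, and JhI-26 (1.29 ± 0.34; adjusted p = 0.0761 with only the 8 libraries of day 4). The list was not called (camera, adjusted p = 0.0511), but was without 1 of replicates 2 and 3 of tumour day 4 or 1 and 3 of control day 4 (adjusted p from 0.015 to 0.0448), and with the replicate block (0.0354), no low-count filter (0.00828), RLE scaling (0.0476) or scaling without the 20 most abundant genes (0.0474). The genes upd3 and Ilp8, signals known from disc tumours, lay under the low-count filter. Over the control and the tumour libraries of day 4, upd3 summed to 3 and 7 counts and Ilp8 to 1 and 88, of which 87 were in a single library.

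RNA of other tissues was also measured in the libraries. Salivary gland markers summed to 1531 CPM in replicate 2 of control day 4 and to between 5.75 and 6.5 CPM in the other 3. Of 12 such markers 7 were called lower with tumours (7 adjusted over the list alone). Gut markers summed to 86.5, 146, 13.4 and 113 CPM in the 4 tumour libraries of day 4 and to 4.44, 13.7, 81.0 and 23.97 CPM in the controls. Of the 9 gut markers tested 1 was called lower, and that list was not called (camera, adjusted p = 0.907). Jon74E, of the Jonah proteases to which some gut markers belong, was at 44.1, 20.6, 38.2 and 32.0 CPM in the same tumour libraries. The ratio of control to tumour, with a 95% exact binomial interval that covers counting error only, was 2685 (743 to 22181) for Eig71Ee, on 2 counts with tumours. It was 2682 (481 to 105964) for Sgs4, on 1 count, 746 (255 to 3620) for Sgs7, on 3 counts, and 787 (218 to 6504) for Sgs8, on 2 counts. Sgs3 was at 584 CPM in that same control library. With only the 8 libraries of day 4 in the model, 1065 genes were called in place of 2191.

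At day 5 the tumour-bearing and control fat bodies differed in 4778 called genes, 2326 higher and 2452 lower with tumours, of which 2195 differed at least 2-fold. Hsp23, a small heat shock protein, was at 7.10 ± 6.47 CPM with tumours and 6391 ± 1276 in controls (-9.80 ± 0.87). Oat was at 1.65 ± 0.46 against 1665 ± 287 (-9.97 ± 0.62) and Fbp1 at 2991 ± 1569 against 270983 ± 21839 (-6.5 ± 0.75). RyR, the ryanodine receptor, was at 39.96 ± 3.73 CPM with tumours and 0.248 ± 0.0714 in controls (7.32 ± 0.21). Cyp4e3 was at 347 ± 74.3 against 2.95 ± 1.01 (6.88 ± 0.44) and CG12522 at 73.7 ± 19.1 against 1.13 ± 1.31 (6.04 ± 0.51). CG14762 (6.56 ± 0.99), CG31886 (6.25 ± 0.52), CG32073 (5.78 ± 0.91), CG43153 (5.76 ± 0.69) and Nepl11 (5.68 ± 0.60) completed the 8 largest rises. Of the largest falls, Drsl5 was 21430 times lower with tumours (95% interval 5932 to 176961, on 2 counts). A scavenger receptor gene of the CD36 family, santa-maria, was 13911 times lower (4760 to 67457, on 3 counts) and CG34206 8515 times (2913 to 41294, on 3 counts), intervals that cover counting error only. CG9812 (-10.99 ± 0.92), CG8850 (-9.70 ± 0.53) and CG5697 (-9.27 ± 0.82) fell as well. Single libraries moved 6 of these values by more than 1.5 times. Without replicate 1 of control day 5 CG12522 rose 7.26 and CG32073 6.91, and without replicate 2 CG14762 rose 7.93. Without replicate 3 of tumour day 5 CG9812 was at -12.45, and without replicate 4 CG8850 was at -10.96 and Hsp23 at -10.53. More genes were higher than lower with scaling that left out the 20 most abundant genes (2417 and 2339), with DESeq2 (2454 and 2453), with no low-count filter (2726 and 2452) and without replicate 3 of tumour day 5 (2400 and 2209).

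The proteasome list was lower with tumours at day 5 in all of its 31 tested members (31 adjusted over the list alone), with a median log2 fold change of -1.16 and Rpn12 at 24.5 ± 1.25 CPM against 69.8 ± 7.58 (-1.51 ± 0.10). Camera called it (adjusted p = 1.08e-23; adjusted p = 0.359 with an estimated correlation). Of 14 genes of protein folding in the endoplasmic reticulum 11 fell and 1 rose (11 and 2 adjusted over the list alone), led by Hsc70-3, the BiP chaperone, at 445 ± 67.9 CPM against 2393 ± 644 (-2.43 ± 0.23). That list was called too (adjusted p = 0.0338; adjusted p = 0.919 with an estimated correlation). It was not called without replicate 3 of tumour day 5 (adjusted p = 0.0602), without replicate 3 of control day 5 (0.0618) or with only the 8 libraries of day 5 (0.0903). Ribosomal proteins were higher with tumours in 78 of 79 members (78 adjusted over the list alone), with a median of 0.81 and RpL22 at 1.18 ± 0.13. Camera's adjusted p for them was 9.98e-24, and adjusted p = 0.545 with an estimated correlation. From day 4 to day 5 their median change was -0.58 in controls and -0.19 with tumours. Among hormone response genes, Hr4 (X, 1941940 to 2007956) was at 1.10 ± 0.308 CPM against 290 ± 57.1 (-8.04 ± 0.51). Eip78C was at 0.476 ± 0.219 against 145 ± 23.9 (-8.21 ± 0.41). Eip93F, the E93 transcription factor of metamorphosis (3R, 21949114 to 22014539), was at 0.370 ± 0.279 against 17.6 ± 6.33 (-5.49 ± 0.46). Of the 20 tested members of the ecdysone response list 11 fell and 5 rose (11 and 5 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.0761). It was called without replicate 3 of tumour day 5 (adjusted p = 0.0278), without replicate 1 of control day 5 (adjusted p = 0.0482) or with only the 8 libraries of day 5 in the model (adjusted p = 0.00054). Kr-h1, a juvenile hormone response gene, also fell (-1.64 ± 0.27), and it was the 1 member of its list to do so. Of the 11 members 4 rose (4 and 1 adjusted over the list alone; median 0.13), among them Jheh1 (1.73 ± 0.11), JhI-26 (1.54 ± 0.37) and Jheh3 (1.45 ± 0.13), and the list was not called (camera, adjusted p = 0.386).

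Transcripts of lipid synthesis genes were higher with tumours at day 5. Of 18 genes 14 were higher and 1 lower (14 and 1 adjusted over the list alone), with a median of 1.13 (camera, adjusted p = 1.26e-05; adjusted p = 0.359 with an estimated correlation). From day 4 to day 5 the summed CPM of the list went from 14985 to 7531 in controls and from 21766 to 20084 with tumours. FASN1, fatty acid synthase (2L, 3056598 to 3068177), was at 4854 ± 666 CPM against 1772 ± 395 (1.45 ± 0.23). Desat1 was at 5664 ± 431 against 722 ± 213 (2.97 ± 0.23), and Men rose 3.0 ± 0.17. Of 15 genes of lipolysis and fatty acid oxidation 11 rose and 1 fell (12 and 1 adjusted over the list alone), including the lipase bmm at 108 ± 15.2 CPM against 63.5 ± 3.23 (0.76 ± 0.17). Camera called this list (adjusted p = 0.0321; adjusted p = 0.663 with an estimated correlation), but not without replicate 3 of control day 5 (adjusted p = 0.0516). Glycolysis rose in 11 of 13 genes (11 adjusted over the list alone), the tricarboxylic acid cycle in 10 of 15 with 2 lower (10 and 2 over the list alone). Oxidative phosphorylation rose in 35 of 46 (36 over the list alone) and glycogen and trehalose metabolism in 7 of 13 with 3 lower (8 and 3 over the list alone). Their camera adjusted p were 0.0036, 0.0036, 0.00138 and 0.0036, and 0.545, 0.545, 0.972 and 0.359 with an estimated correlation. The last was 0.0534 by camera's rank test. Tps1, trehalose phosphate synthase, was at 1.68 ± 0.09 and Ogdh at 2.46 ± 0.15. In amino acid catabolism 8 of 13 genes rose and 2 fell (9 and 2 over the list alone), with Sam-S at 2.38 ± 0.18 and Gnmt at 2.19 ± 0.29. Its camera test gave adjusted p = 0.0339, and adjusted p = 0.484 with an estimated correlation. Its median was 0.84, or 1.46 without replicate 1 of control day 5. The call was lost without replicate 2 of control day 5 (0.0756) and with only the 8 libraries of day 5 (0.157).

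ImpL2 was again higher at day 5, at 280 ± 71.4 CPM against 126 ± 16.2 (1.16 ± 0.16), and tobi was at 272 ± 80.7 against 12.03 ± 8.24 (4.5 ± 0.52). Thor was lower, at 421 ± 26.8 against 1047 ± 130 (-1.31 ± 0.27). Of 12 genes of the JAK/STAT pathway and its responses 9 rose and 3 fell (9 and 3 adjusted over the list alone), with TotC at 223 ± 39.8 CPM against 4.92 ± 1.48 (5.5 ± 0.34) and Socs36E at 1.8 ± 0.26. The list was called with only the 8 libraries of day 5 in the model (camera, adjusted p = 0.034) but not with all 24 (adjusted p = 0.0868). Antimicrobial peptides were called lower in 4 of 14 cases and higher in none (3 and 0 adjusted over the list alone). NimC2, a phagocytic receptor gene of the haemocyte list, was at 42.5 ± 28.5 CPM against 4115 ± 679 (-6.6 ± 0.67). Hml (1.92 ± 0.27), Sr-CI (2.0 ± 0.28) and PPO2 (1.86 ± 0.38) of the same list were higher with tumours. Lsp2 did not pass the test (-0.12 ± 0.16). Counts of upd3 summed to 3 in controls and 17 with tumours, and those of Ilp8 to 0 and 74, 72 of them in a single library. Gut markers summed to 372 and 255 CPM in replicates 1 and 2 of tumour day 5, to 263 and 162 in replicates 1 and 4 of control day 5 and to at most 7.21 in the other 4 libraries. Testis markers summed to 177 CPM in replicate 1 of tumour day 5, and salivary gland markers to 1491 CPM in replicate 3 of control day 5.

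**Figure D1:**
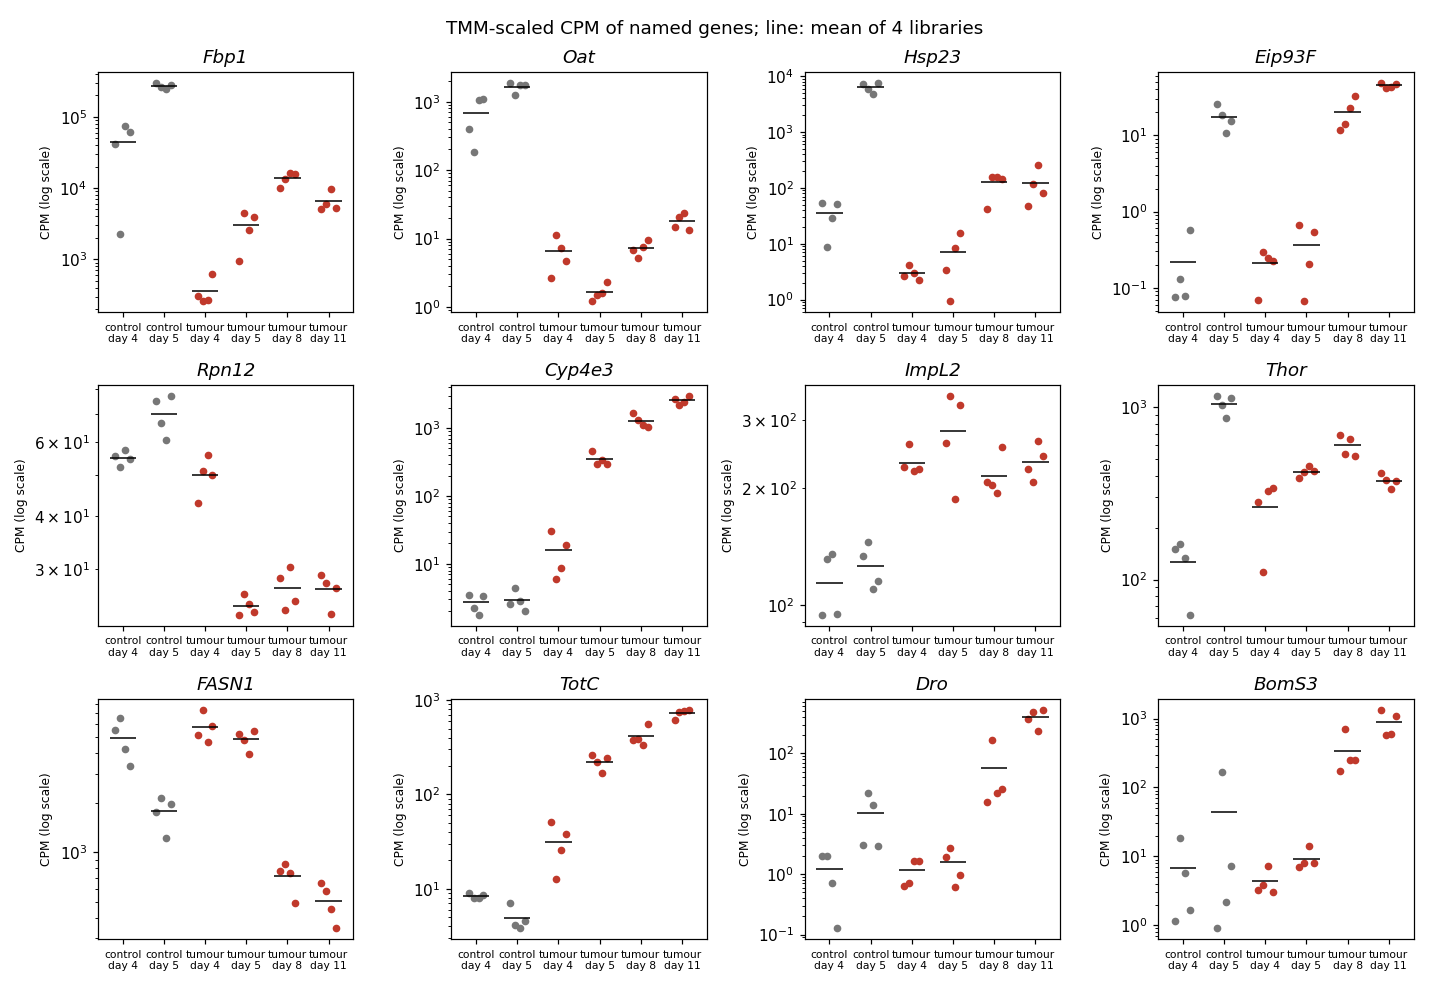
Normalised read counts (CPM, log axis) of 12 named genes in each of the 24 libraries (points, with a horizontal line at the mean of 4), by group and day. Fbp1 reached 270983 CPM on average in controls of day 5 and 13847 CPM with tumours at day 8, and Dro rose to 402 CPM at day 11.

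The tumour effect itself was then compared between days 5 and 4 by testing the difference of the differences. It changed in 2511 genes, 1050 higher and 1461 lower at day 5, of which 1225 changed at least 2-fold. The effect on Hr4 fell by 7.91 (SE 0.75), and those on CG5697 (-11.51 ± 1.31) and CG1607 (-8.64 ± 0.92) were also among the 5 largest falls. Those on Cyp4e3 (4.34 ± 0.55) and CG12522 (5.43 ± 0.85) rose. Obp44a (7.72 ± 1.81) also met the naming rule, with 82.0 CPM in replicate 4 of control day 4 and at most 0.613 CPM in the other 3. Its value was 2.43 without that library and 6.48 without replicate 1 of tumour day 5. CG12715 met the rule with 97.0 CPM in replicate 2 of control day 4 and 1 count over the tumour libraries of that day, and Drsl5 with 2 counts over the tumour libraries of day 5. All 31 proteasome genes had a lower tumour effect at day 5 (31 adjusted over the list alone; median -1.07; camera, adjusted p = 2.91e-31, and adjusted p = 0.364 with an estimated correlation). The tumour effect was higher at day 5 for 40 of 79 ribosomal protein genes (48 adjusted over the list alone; camera, adjusted p = 1.66e-09, and adjusted p = 0.889 with an estimated correlation). It was also higher for 10 of 18 genes of fatty acid synthesis and lower for 1 (10 and 1 over the list alone; camera, adjusted p = 0.000502, and adjusted p = 0.889 with an estimated correlation). Thor differed between the days (-2.37 ± 0.38), as did FASN1 (1.23 ± 0.32), Lsp2 (0.67 ± 0.22), Kr-h1 (-1.05 ± 0.38) and Eip93F (-5.41 ± 1.07). For Fbp1 (0.44 ± 0.83), ImpL2 (0.12 ± 0.23), bmm (0.38 ± 0.24) and scrib (-0.08 ± 0.14) the difference did not pass the test. The call of Kr-h1 ended without 1 of replicates 1 and 4 of tumour day 4, 1 and 2 of tumour day 5, 2 and 4 of control day 4 or any of control day 5 (adjusted p from 0.0554 to 0.113) and under RLE scaling (adjusted p = 0.0544). It also ended with scaling that left out the 20 most abundant genes (0.066), no low-count filter (0.056), only these 16 libraries (0.129), and without the day 5 tumour libraries with gut or testis RNA (0.204) or the 2 controls with the most salivary gland RNA (0.0891), chosen after the data were seen. The call of Lsp2 ended without replicate 2 or 3 of tumour day 4 or replicate 1 of either control group (adjusted p from 0.0506 to 0.0604), with no low-count filter (0.0531) and with only these 16 libraries (0.0694). Leaving out 1 library moved Eip93F to -6.58 (without replicate 4 of control day 4) and CG12522 to 6.65 (without replicate 1 of control day 5). CG5697 was at -10.78 without replicate 1 of tumour day 4 and at -12.12 without replicate 4 of control day 4. Across the 8707 genes the log2 fold changes of both days, which share no library, had a Pearson r of 0.449 and a Spearman rho of 0.436. Genes are not independent replicates. Of the genes called higher, 920 were shared between the days, against 340 for independent lists, and of those called lower 680, against 258.

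Control fat body from day 4 to day 5 gave the course of normal development, with 4790 called genes, 2246 higher and 2544 lower at day 5, and 1987 changed at least 2-fold. CG9812 rose from 3.73 ± 0.901 to 2446 ± 614 CPM (9.35 ± 0.85), santa-maria from 1.05 ± 0.579 to 578 ± 164 (9.07 ± 0.62). Drsl5 rose from 1.30 ± 0.459 to 594 ± 203 (8.82 ± 0.95) and Hsp23 by 7.49 ± 0.79. CG5697 (9.60 ± 0.86), CG34206 (9.38 ± 0.95), lncRNA:CR45593 (8.13 ± 0.62), CG17739 (8.05 ± 0.47) and CG8850 (7.97 ± 0.47) were the other leading rises. Among the largest falls under the naming rule were GstD7 (-4.24 ± 0.59) and GstD6 (-3.15 ± 0.34), glutathione S-transferases. The yolk protein gene Yp3 fell from 710 ± 183 to 51.7 ± 38.3 CPM (-3.78 ± 0.41), and so did Akr1B (-3.58 ± 0.38), Est-6 (-3.01 ± 0.57), Ugt35A1 (-2.97 ± 0.34) and the gene FBgn0040813 (-3.73 ± 0.60). CG13560 was 1406 times lower (95% interval 389 to 11615 for counting error only, on 2 counts), with 159 CPM in replicate 2 of day 4 and at most 1.07 CPM in the other 3. That library also set the size of other falls. Without it GstD7 was at -3.44, FBgn0040813 at -2.88, Akr1B at -2.99 and Est-6 at -2.12. Without replicate 4 of day 4 the rises of CG34206 and CG5697 were 9.996 and 10.21. Without its replicate 3 that of lncRNA:CR45593 was 8.91, and without replicate 4 of day 5 Yp3 was at -4.39. Fewer genes were lower than higher under RLE scaling (2377 higher and 2329 lower), with DESeq2 (2446 and 2396) and with only these 8 libraries (2069 and 2019).

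The ecdysone response list rose in 12 of 20 genes and fell in 4 (12 and 5 adjusted over the list alone), with Hr4 at 7.75 ± 0.51, Eip78C at 7.35 ± 0.39 and Eip93F at 6.23 ± 0.52, or 7.40 without replicate 4 of day 4. For this list camera gave adjusted p = 0.00152, and adjusted p = 0.282 with an estimated correlation. Of 24 autophagy and lysosome genes 17 rose and 1 fell (17 and 1 adjusted over the list alone), with Atg7 at 181 ± 39.7 CPM from 17.1 ± 1.70 (3.41 ± 0.19) and the protease gene cathD at 1.92 ± 0.23 (camera, adjusted p = 6.16e-05, and adjusted p = 0.549 with an estimated correlation). Of 31 proteasome genes 19 rose and 2 fell (19 and 2 over the list alone; camera, adjusted p = 0.0285, and adjusted p = 0.892 with an estimated correlation). That call was lost without replicate 1 (0.0635) or 4 (0.0748) of day 5. All 46 oxidative phosphorylation genes fell (46 adjusted over the list alone; median -1.47), as did 78 of 79 ribosomal protein genes (78 over the list alone; median -0.58). So did 17 of 18 genes of fatty acid synthesis (17 over the list alone; median -1.19) and 11 of 13 glycolysis genes (11 over the list alone; median -1.36). Their camera adjusted p were 2.37e-28, 6.79e-14, 2.97e-05 and 2.69e-09, and 0.325, 0.618, 0.325 and 0.231 with an estimated correlation. Thor rose 3.04 ± 0.28, Kr-h1 1.45 ± 0.27, Fbp1 2.60 ± 0.62 and NimC2 3.20 ± 0.57, and FASN1 fell (-1.47 ± 0.23). ImpL2 (0.15 ± 0.16), bmm (-0.01 ± 0.17), Lsp2 (-0.11 ± 0.16) and scrib (0.14 ± 0.10) did not pass the test.

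In tumour-bearing larvae over the same day 3834 genes were called, 1705 higher and 2129 lower at day 5, with 1387 changed at least 2-fold. Here the proteasome fell in 30 of 31 genes (31 adjusted over the list alone; median -0.79; camera, adjusted p = 4.76e-20, and adjusted p = 0.212 with an estimated correlation). In the same larvae 12 of 14 endoplasmic reticulum folding genes fell while 1 rose (12 and 1 over the list alone; median -1.44; camera, adjusted p = 1.17e-08, and adjusted p = 0.15 with an estimated correlation). All 46 oxidative phosphorylation genes fell (46 over the list alone; median -1.51; camera, adjusted p = 1.89e-44, and adjusted p = 0.15 with an estimated correlation), as in controls. The laminin gene LanB1 fell from 313 ± 64.6 to 38.1 ± 10.5 CPM (-3.04 ± 0.21). The insulin and FOXO list rose in 8 of 16 genes and fell in none (9 and 0 over the list alone), with InR at 1.24 ± 0.18 and Ilp6 at 1.23 ± 0.21. The list was called (camera, adjusted p = 0.00531, and adjusted p = 0.244 with an estimated correlation). Fbp1 rose 3.04 ± 0.64, Thor 0.67 ± 0.26 and Lsp2 0.56 ± 0.16. FASN1 (-0.24 ± 0.23), Eip93F (0.82 ± 0.73), ImpL2 (0.27 ± 0.16), bmm (0.37 ± 0.17), Kr-h1 (0.41 ± 0.27) and scrib (0.07 ± 0.10) did not pass the test. The call of Thor ended without replicate 1 or 2 of day 4 or any 1 library of day 5 (adjusted p from 0.0555 to 0.126), with no low-count filter (0.0682), with only these 8 libraries (0.0823), with the replicate block (0.0514) and without the day 5 libraries that held gut or testis RNA (0.0923). ImpL2 was called without replicate 3 of day 5 (0.49, adjusted p = 0.00972) and bmm without replicate 4 of day 4 (0.55, adjusted p = 0.0105) or under RLE scaling (0.45, adjusted p = 0.0392), scaling without the 20 most abundant genes (0.0399) and DESeq2 (0.0271). The balance of directions also turned, with 2003 genes higher and 1870 lower under RLE scaling, 1939 and 1898 without the 20 most abundant genes in the scaling, and 2112 and 1929 with DESeq2. The log2 fold changes from day 4 to day 5 in controls and with tumours had r = 0.367 and rho = 0.421 across 8707 genes. Of the called genes 885 rose in both, against 440 for independent lists, and 1431 fell in both, against 622.

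**Figure D2:**
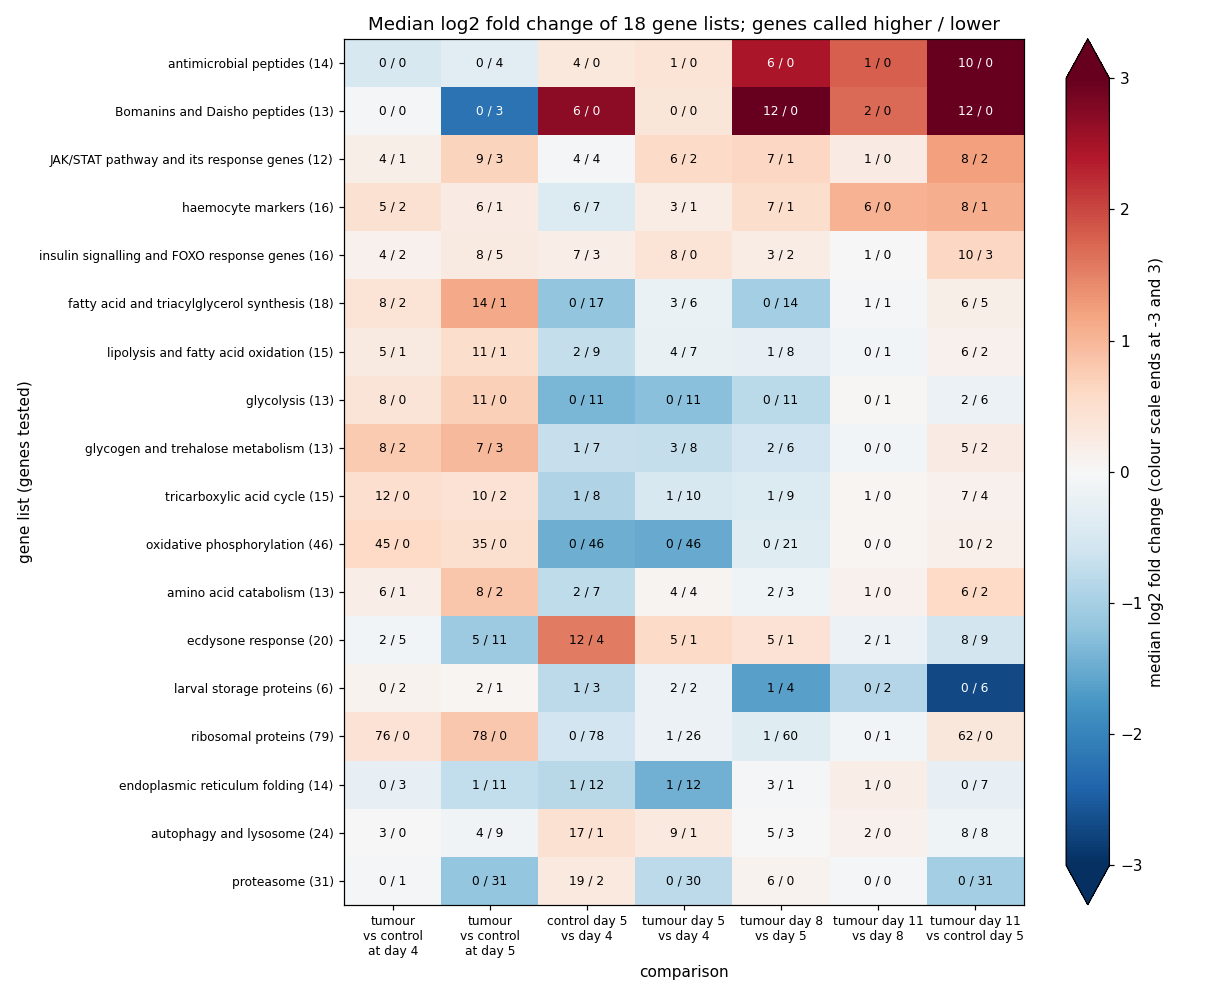
Median log2 fold change of the tested members of 18 gene lists (vertical axis) in 7 comparisons (horizontal axis), with red for higher and blue for lower and the number of members called higher and lower printed in each cell. The proteasome median was -1.16 in tumours against controls at day 5 and the Bomanin median 5.13 from day 5 to day 8 with tumours, or 4.46 without replicate 2 of day 8.

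From day 5 to day 8 of tumour growth 2270 genes changed, 1047 higher and 1223 lower at day 8, with 768 at least 2-fold. Of 13 Bomanin and Daisho genes, short secreted peptides known as targets of the Toll pathway, 12 were higher at day 8 (13 adjusted over the list alone), with a median log2 fold change of 5.13, or 4.46 without replicate 2 of day 8. BomT2 (2R, 18388995 to 18389443) rose from 0.372 ± 0.137 to 25.96 ± 9.30 CPM (6.09 ± 0.62) and BomS3 from 9.25 ± 3.34 to 343 ± 242 (5.21 ± 1.2). BomBc1 rose 5.83 ± 1.32 and BomBc2 5.13 ± 1.15. Of 14 antimicrobial peptide genes 6 rose (7 adjusted over the list alone). The median of the 14 was 2.44, but 0.73 without replicate 2 of day 8, 3.13 without replicate 1 of day 5 and 5.23 without both day 5 libraries that held gut or testis RNA, the last chosen after the data were seen. The rises included Dro, drosocin (2R, 14745961 to 14746714), from 1.57 ± 0.961 to 58.1 ± 73.8 CPM (5.23 ± 0.87), DptA at 4.32 ± 1.00 and Mtk at 4.26 ± 0.89. Replicate 2 of day 8 had the highest levels, and without it BomBc1 rose 4.60, BomS3 4.59, Dro 3.78, DptA 3.06 and Mtk 3.17, all still called. DptA rose 4.94 without replicate 1 of day 5. In the JAK/STAT list 7 of 12 genes rose and 1 fell (8 and 1 over the list alone), with TotB at 3.11 ± 0.32. Camera called these 3 lists (adjusted p = 1.15e-05, 0.00654 and 0.000848; adjusted p = 0.584, 0.622 and 0.184 with an estimated correlation). Haemocyte markers rose in 7 of 16 genes and fell in 1 over the same days (7 and 2 adjusted over the list alone; median 0.53), with He at 1.75 ± 0.28, eater at 1.61 ± 0.31 and Hml at 1.44 ± 0.26. Camera called them (adjusted p = 0.00929; adjusted p = 0.622 with an estimated correlation, and 0.0673 by its rank test).

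Fatty acid synthesis genes fell from day 5 to day 8, in 14 of 18 cases and with none higher (15 adjusted over the list alone; median -1.01). It was the 1 list called also with an estimated correlation (camera, adjusted p = 1.49e-14, and adjusted p = 0.0317 with an estimated correlation). FASN1 fell from 4854 ± 666 to 715 ± 157 CPM (-2.76 ± 0.24) and ACC by 2.04 on the log2 scale (SE 0.35). Agpat2 fell from 53.6 ± 8.76 to 3.34 ± 0.537 CPM (-4.0 ± 0.28). Glycolysis fell in 11 of 13 genes (11 lower and 1 higher adjusted over the list alone; camera, adjusted p = 3.39e-10, and adjusted p = 0.0738 with an estimated correlation). Ribosomal proteins fell in 60 of 79 cases with 1 higher (67 and 1 over the list alone; camera, adjusted p = 1.78e-15, and adjusted p = 0.622 with an estimated correlation). Of 6 storage protein genes 4 fell and 1 rose (4 and 1 over the list alone; camera, adjusted p = 0.000272, and adjusted p = 0.184 with an estimated correlation). Lsp1alpha fell from 32333 ± 14599 to 2130 ± 1470 CPM (-3.92 ± 0.55), and Fbp1 rose 2.21 ± 0.61. The share of all counts held by these 6 genes was 42.8% ± 1.96 and 41.0% ± 1.49 in controls of days 4 and 5, and 40.7% ± 1.53, 32.1% ± 4.31, 14.7% ± 3.68 and 7.23% ± 1.37 with tumours at days 4, 5, 8 and 11. Fbp1 is 1 of these 6 genes. It held most of the share in controls of day 5 but little of it with tumours at that day. The shares therefore do not give the course of the other storage protein genes. Eip93F rose from 0.370 ± 0.279 to 20.2 ± 9.45 CPM (5.70 ± 0.46). CtsL3, a cathepsin-like protease (3R, 6025826 to 6027238), rose from 4.21 ± 1.87 to 422 ± 191 (6.64 ± 0.42). Genes that fell were sro (-4.33 ± 0.30), CG3348 (-4.34 ± 0.46), Yp3 (-3.79 ± 0.44), CG10962 (-3.56 ± 0.29), CG3609 (-3.0 ± 0.26) and the lipase bmm (-0.48 ± 0.17). ImpL2 (-0.38 ± 0.16), Thor (0.51 ± 0.26), Lsp2 (-0.30 ± 0.16), Kr-h1 (0.42 ± 0.26) and scrib (0.02 ± 0.10) did not pass the test. Without replicates 1 and 2 of tumour day 5, which held gut or testis RNA, 1193 genes were called in place of 2270, a setting chosen after the data were seen. In that setting BomBc1 (adjusted p = 0.0511), BomBc2 (adjusted p = 0.0584), BomS3 (adjusted p = 0.0645), Fbp1 (adjusted p = 0.0852) and bmm (adjusted p = 0.0638) did not pass. The call of bmm ended without 1 of replicates 2, 3 and 4 of day 5 or 1, 2 and 3 of day 8 (adjusted p from 0.0658 to 0.133) and with no low-count filter (0.0713). Thor was called higher with only these 8 libraries in the model (adjusted p = 0.00696), and ImpL2 was called lower without replicate 3 of day 5 (-0.56, adjusted p = 0.00716) and with scaling that left out the 20 most abundant genes (-0.44, adjusted p = 0.0454).

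From day 8 to day 11 the change was smaller in number of genes: 291 were called, 150 higher and 141 lower, 99 of them at least 2-fold. Cyp309a2 rose from 6.61 ± 3.43 to 74.1 ± 19.0 CPM (3.48 ± 0.46) and edin, an immune-induced secreted peptide, by 3.43 ± 0.80. Dro rose from 58.1 ± 73.8 to 402 ± 132 CPM (2.79 ± 0.72), as did BomS6 (2.38 ± 0.39), BomT2 (2.0 ± 0.43) and CG43402 (2.13 ± 0.25). Gs2, glutamine synthetase (-1.99 ± 0.53), Lsp1beta, from 62835 ± 26595 to 19735 ± 6968 CPM (-1.67 ± 0.26), Obp99b (-1.35 ± 0.23), Tsp42Ek (-1.43 ± 0.29), Nt5a (-1.2 ± 0.21) and Root (-1.19 ± 0.14) fell. Of 14 antimicrobial peptides 1 was called higher (1 adjusted over the list alone) and of 13 Bomanins 2 (5 over the list alone). The medians of these lists were 1.79 and 1.71, or 3.46 and 2.68 without replicate 2 of day 8, and camera called both (adjusted p = 1.34e-05 and 5.67e-06; adjusted p = 0.454 for both with an estimated correlation). Haemocyte markers rose in 6 of 16 genes (7 over the list alone; median 1.05), with Hml at 253 ± 48.7 CPM at day 11, NimC1 at 1.47 ± 0.21 and eater at 1.67 ± 0.30. Their camera adjusted p was 1.2e-05, with adjusted p = 0.353 with an estimated correlation and 0.0885 by the rank test. The number of calls was 187 with no low-count filter, 835 with only these 8 libraries in the model and 559 with DESeq2. It was 137, 177, 170, 141 and 167 without replicates 1 and 2 of day 8 and 2, 3 and 4 of day 11. The call of Gs2 ended without any 1 of the 8 libraries (adjusted p from 0.0556 to 0.133), and that of Dro without any 1 but replicate 2 of day 8 (from 0.0513 to 0.116; a rise of 4.24 without that library). The call of edin ended without replicate 1, 3 or 4 of day 8 or replicate 2 of day 11 (from 0.0503 to 0.168; 2.33 without the last). With only these 8 libraries Dro (0.11) and edin (0.077) were not called. With no low-count filter Dro (0.0764) and Gs2 (0.103) were not called, nor Gs2 with the replicate block (0.0671), and DESeq2 did not call BomT2 (0.103). Without replicate 3 of day 8, 102 genes were higher and 115 lower. Of the genes named in every comparison none was called, with Eip93F at 1.15 ± 0.33, Fbp1 at -1.09 ± 0.59, Thor at -0.68 ± 0.26, FASN1 at -0.50 ± 0.23, bmm at 0.49 ± 0.17, scrib at 0.22 ± 0.10, ImpL2 at 0.12 ± 0.16, Kr-h1 at 0.04 ± 0.26 and Lsp2 at 0.02 ± 0.16. Eip93F was called higher without replicate 4 of day 8 (1.48, adjusted p = 0.0233), with the replicate block (0.0463) and with DESeq2 (0.0305). With only these 8 libraries Fbp1 (0.0287), Thor (0.00477) and bmm (0.0217) were called. Counts of upd3 summed to 12 at day 8 and 23 at day 11, and those of Ilp8 to 12 and 5.

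For days 8 and 11 the nearest control was that of day 5, so age and tumour differ together in this comparison. It called 4733 genes at day 8, 2190 higher and 2543 lower, and 5009 at day 11, 2389 higher and 2620 lower. Of these 2145 and 2350 changed at least 2-fold. With only these 8 libraries in the model, 2810 genes were higher and 2421 lower at day 11. Cyp4e3 was at 2572 ± 313 CPM at day 11 against 2.95 ± 1.01 (9.77 ± 0.49) and CG8299 at 40.03 ± 7.52 against 0.0635 ± 0.0562 (9.21 ± 0.56). CG14762 was at 331 ± 40.1 against 0.704 ± 0.901 (8.94 ± 1.05), CG14275 rose 7.81 ± 0.60 and the defensin gene Def 8.72 ± 1.59. At day 11, of 13 Bomanin and Daisho genes 12 were higher (12 adjusted over the list alone; median 4.28; camera, adjusted p = 0.00324, and adjusted p = 0.871 with an estimated correlation). These genes summed to 376 CPM in replicate 2 of control day 5 and to at most 17.8 in the other 3, and without that library the median at day 11 was 8.045. Of 14 antimicrobial peptide genes, Def included, 10 were higher at day 11 (10 over the list alone; median 3.44), but the list was not called (camera, adjusted p = 0.0691). It was called without replicate 1 (0.0486) or 3 (0.0408) of day 11 or replicate 2 of control day 5 (0.0233; median 4.84), with the replicate block (0.0205), no low-count filter (0.00189) and by the rank test (0.00297). All 6 storage protein genes were lower (6 over the list alone; median -2.71; camera, adjusted p = 0.00417, and adjusted p = 0.662 with an estimated correlation), with Lsp2 at -0.40 ± 0.16 and Fbp1 at 6497 ± 2204 CPM (-5.38 ± 0.71). So were all 31 proteasome genes (31 over the list alone; median -1.02; camera, adjusted p = 5.34e-19, and adjusted p = 0.662 with an estimated correlation). ImpL2 (0.90 ± 0.16), bmm (0.77 ± 0.17) and Eip93F, at 44.8 ± 3.66 CPM (1.35 ± 0.33), were higher. Thor (-1.48 ± 0.27), FASN1 (-1.81 ± 0.23) and Kr-h1 (-1.18 ± 0.26) were lower, and scrib (-0.06 ± 0.10) did not pass. The call of Lsp2 at day 11 ended without 1 of replicates 1, 3 and 4 of day 11 or 2, 3 and 4 of control day 5 (adjusted p from 0.0504 to 0.0886) or with no low-count filter (0.0552). Without replicate 2 of control day 5 CG14762 rose 10.30 and Def 9.64. CG34206 was 42073 times lower, on 1 count over the day 11 libraries (95% interval 7551 to 1661872 for counting error only). Sgs3, Sgs5, Sgs8 and Sgs7, genes of the salivary glue, were 25363, 6315, 4689 and 3621 times lower, on 1, 1, 1 and 2 counts. The intervals were 4551 to 1001871, 1133 to 249484, 841 to 185271 and 1002 to 29908, and replicate 3 of control day 5 held 659 CPM of Sgs3. The day 5 tumour effect and the change from day 8 to day 11, which share no library, had r = 0.041 and rho = 0.0161 across 8707 genes.

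At day 8 against the same controls, 9 of 13 Bomanin and Daisho genes were higher (9 adjusted over the list alone; median 2.71) and 5 of 6 storage protein genes lower (5 over the list alone; median -1.54), but neither list was called (camera, adjusted p = 0.0544 and 0.074). The Bomanin list was called without 1 of replicates 1, 3 and 4 of day 8 or 2 and 4 of control day 5 (adjusted p from 0.000102 to 0.0456; median 6.59 without replicate 2 of control day 5). It was also called with the replicate block (0.0272), no low-count filter (0.00136), scaling without the 20 most abundant genes (0.0405) and by the rank test (0.00438). The storage protein list was called without replicate 1 of day 8 (0.0214) or 1 (0.0444) or 4 (0.0456) of control day 5, with the replicate block (0.0429), no low-count filter (0.00311), only these 8 libraries (0.00247) and by the rank test (0.0287). Antimicrobial peptides were higher in 4 of 14 cases (3 over the list alone; camera, adjusted p = 0.319). All 31 proteasome genes were lower (31 over the list alone; median -0.97; camera, adjusted p = 1.29e-20, and adjusted p = 0.59 with an estimated correlation). ImpL2 (0.77 ± 0.16) was higher, and Fbp1 (-4.29 ± 0.67), FASN1 (-1.31 ± 0.23), Kr-h1 (-1.22 ± 0.26), Thor (-0.80 ± 0.26), Lsp2 (-0.42 ± 0.16) and scrib (-0.28 ± 0.10) were lower. Eip93F (0.20 ± 0.33) and bmm (0.28 ± 0.17; adjusted p = 0.0289 with only these 8 libraries) did not pass. The call of Lsp2 ended without replicate 2, 3 or 4 of day 8 (adjusted p from 0.0521 to 0.0614), and that of scrib without replicate 1 of day 8 (0.0622) or replicate 2 of control day 5 (0.0551).

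**Figure D3:**
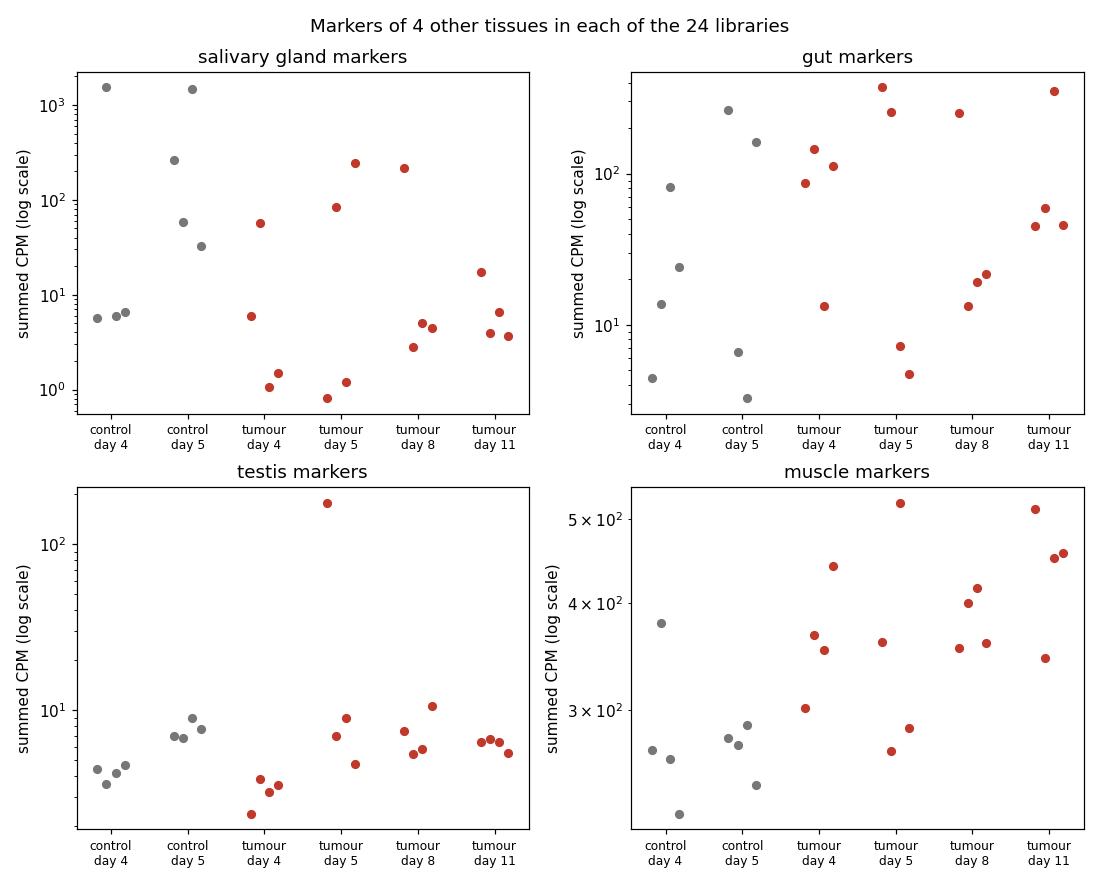
Summed CPM (log axis) of markers of 4 other tissues in each of the 24 libraries, by group. Salivary gland markers reached 1531 and 1491 CPM in single control libraries of days 4 and 5, and testis markers 177 CPM in a single tumour library of day 5.

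**Figure D4:**
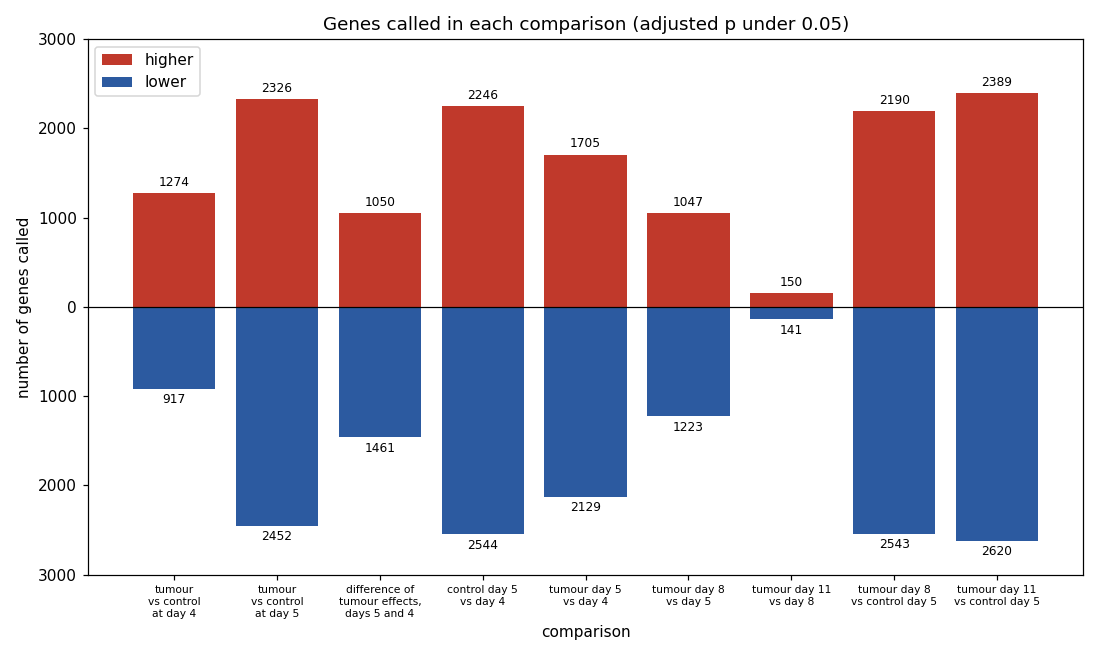
Number of genes called in each of the 9 comparisons, higher (above the line) and lower (below it), by edgeR's quasi-likelihood test. Counts ran from 291 genes between tumour days 11 and 8 to 5009 between tumour day 11 and control day 5.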

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

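The tests of slower development as the whole cause and of salivary gland, haemocyte and gut RNA were chosen only after the results they bear on had been seen. Of 524 genes called at least 4-fold higher in control day 5 than day 4, 36.5% were called higher with tumours at day 5 than at day 4, 70.8% at day 8 and 69.1% at day 11, against 19.6%, 28.3% and 29.9% of all genes tested. Proteasome genes, of which 19 of 31 rose in controls, had a median of -0.87 in tumour day 5 against control day 4. They were called lower there in 31 of 31 cases. For these genes that argues against slower development along a steady course between the control days as the whole cause. For this test the list was picked when its lower level with tumours at day 5 was known, and it is not the set of 524 genes. A passing fall between the control days was not sampled, so slower development is not excluded. The 2 control libraries with the most salivary gland RNA held 1531 and 1491 CPM of its markers, and only the second is of day 5. Without both, 95.35% of the genes called lower with tumours at day 5 stayed so. So did 98.8% of the 424 that had also risen at least 4-fold in controls. Of all 4778 genes called at day 5, 4445 stayed called without both, and 4267 to 4487 without any 1 library of day 5. The calls thus did not rest on that day 5 control. Since any library gave a similar share, the test cannot decide on a part of salivary gland RNA beyond that. The other 3 controls of day 5 held 32.4 to 262 CPM of these markers and the tumour libraries of that day 0.811 to 247, and the part of these smaller amounts was not tested. A later start of the same rises goes with the 70.8% and may account for part of the pattern as a hypothesis. Against tumour day 4 the median log2 change of the 524 genes was 2.01 at day 8 and 2 at day 11. In controls it was 3.11. Of 197 genes at least 4-fold lower in control day 5 than day 4, 50.8% were called lower with tumours at day 8 and 48.7% at day 11. Among all genes tested these shares were 31.4% and 32.8%. Whether the tumour or the longer larval life delays these genes was not tested, since no control of day 8 is used here. The driver was the same in both genotypes.

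Proteasome transcripts were lower with tumours at day 5 in 31 of 31 genes, with a median of -1.16. With the 20 most abundant genes left out of the scaling the median was -1.134, which argues against a few storage protein genes setting it. Among 10000 random sets matched on exon length and mean expression, 0% had a median as low and the lowest was -0.596, which argues against transcript length. With an estimated correlation between genes camera did not call the list at day 5. A lower expression of the proteasome in tumour-bearing larvae may be biological, as an untested hypothesis from the same data, and the sign was opposite in the course of controls.

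Bomanin transcripts rose from day 5 to day 8 with tumours, with a median of 5.13, or 4.46 without replicate 2 of day 8. A larger amount of otherwise unchanged haemocyte RNA would raise haemocyte markers as much. The highest of them, NimC2, rose 2.89 (SE 0.564), which argues against that amount alone. Camera did call these markers higher as a list at the preset correlation. Markers need not rise if haemocytes themselves made more of these peptides, so the test cannot decide on a part of haemocytes. The median of 9 gut markers was at -1.25, but this fall goes with high gut marker sums in replicates 1 and 2 of day 5. It therefore cannot weigh gut RNA at day 8, where these markers summed to 250 CPM in replicate 1 and to 13.2 to 21.6 CPM in the others. Bomanin and Daisho genes summed to 15.9 ± 4.92 CPM at day 5, with those gut-rich libraries included, and to 571 ± 431 CPM at day 8. Gut RNA alone is thus argued against. Without any 1 of the 8 libraries at least 9 of 13 Bomanin and Daisho genes stayed called higher, which argues against a single library. An immune response of the fat body to the ageing tumour or to microbes in the longer larval life may be a candidate explanation, and age and tumour stay open, since no library without tumours at day 8 is used here.

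Chance flags about 1 in 20 groups of 4 libraries as having a library far from the others, and 17 of 144 groups had one. Total counts were 16477328 in replicate 2 of control day 5 and at least 19103824 in the other 3. Gut markers summed to 250.4 CPM in replicate 1 of tumour day 8 (others at most 21.6) and 349 CPM in replicate 3 of tumour day 11 (others at most 59.6). Salivary gland markers summed to 1531 CPM in replicate 2 of control day 4 (others at most 6.5) and 1491 CPM in replicate 3 of control day 5 (others at most 262). They summed to 57.6 CPM in replicate 2 of tumour day 4 (others at most 5.96) and 219 CPM in replicate 1 of tumour day 8 (others at most 5.01). Testis markers summed to 177 CPM in replicate 1 of tumour day 5, with at most 8.92 in the others. Both roX RNAs summed to 124 CPM in replicate 2 of tumour day 5, with 239.98 to 252 in the others. Ribosome biogenesis genes summed to 1469 CPM in replicate 2 of control day 4 (others at most 841) and 1290.3 CPM in replicate 3 of control day 5 (others at most 683), the 2 libraries with most salivary gland RNA. BomS3 was at 14.2 CPM in replicate 3 of tumour day 5 (others at most 7.92). It was at 703 CPM in replicate 2 of tumour day 8 (others at most 249), the library in which Dro also stood apart, at 169 CPM (others at most 25.9). CG14762 was at 2.05 CPM in replicate 2 of control day 5 (others at most 0.303), Fbp1 at 614 CPM in replicate 4 of tumour day 4 (others at most 307) and ImpL2 at 259 CPM in replicate 2 of tumour day 4 (others at most 226).

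The tumour effect differed between days 5 and 4 by the test of the difference in 2511 of 8707 genes and in 3 lists. It also differed in 18 of 24 named genes compared. Some of these, such as CG5697, CG1607 and Obp44a, were named because their difference was called and large. The share of named genes is thus partly set by that choice. Median differences were 0.74 for fatty acid synthesis, 0.38 for ribosomal proteins and -1.07 for the proteasome, and none of the 3 was called with an estimated correlation (adjusted p = 0.889, 0.889 and 0.364). The effect on genes was higher at day 5 by 5.43 for CG12522, 4.34 for Cyp4e3, 1.61 for Desat1, 1.23 for FASN1, 0.57 for Jheh1, 0.78 for Jheh3, 0.67 for Lsp2, 1.5 for Men, 2.05 for Nepl11, 7.72 for Obp44a and 3.59 for TotC. It was lower at -8.64 for CG1607, -11.51 for CG5697, -5.41 for Eip93F, -7.91 for Hr4, -1.05 for Kr-h1, -3.28 for Oat and -2.37 for Thor. Single libraries moved Obp44a to 2.43 (without replicate 4 of control day 4) and 6.48 (without replicate 1 of tumour day 5), CG12522 to 6.65 (without replicate 1 of control day 5) and Eip93F to -6.58 (without replicate 4 of control day 4). CG5697 was at -10.78 without replicate 1 of tumour day 4 and at -12.12 without replicate 4 of control day 4. The call of Kr-h1 ended without 1 of replicates 1 and 4 of tumour day 4, 1 and 2 of tumour day 5, 2 and 4 of control day 4 or any of control day 5 (adjusted p up to 0.113). Lsp2 lost its call without replicate 2 or 3 of tumour day 4 or replicate 1 of either control group (adjusted p up to 0.0604). Nepl11 lost it without 1 of replicates 1, 2 and 4 of tumour day 4, 1 and 2 of tumour day 5, 1 and 2 of control day 4 or 2, 3 and 4 of control day 5 (adjusted p from 0.0513 to 0.229; 1.10 without replicate 2 of control day 4 and 1.52 without replicate 1 of tumour day 5).

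Other splits of the same 8 libraries into groups of 4 were tested for each comparison of 2 groups. In all 8 comparisons 1 of 35 splits, the real one, gave as many genes. That is the smallest share that 35 splits allow, and 8 comparisons were made. Chance is thus an unlikely source of the counts but is not excluded. The real counts and the highest of the other splits were 2191 and 1174 for tumour against control at day 4, 4778 and 2 at day 5, 4790 and 1065 for control day 5 against day 4, and 3834 and 1148 for tumour day 5 against day 4. They were 2270 and 3 for day 8 against day 5, 291 and 3 for day 11 against day 8, 4733 and 0 for tumour day 8 against control day 5 and 5009 and 1 for day 11. The splits with 1174, 1065 and 1148 genes each exchanged 1 library between the groups. These were replicate 2 of control day 4 with replicate 1 of tumour day 4, replicate 4 of control day 4 with replicate 3 of control day 5, and replicate 1 of tumour day 4 with replicate 1 of tumour day 5. Why these exchanges gave more genes than others was not tested. For the difference between the tumour effects 6 of 100 drawn splits of 16 libraries gave as many genes, with 2511 in the real split and 3788 in the highest other. The other 5 kept the libraries of both day 5 groups whole and so hold the tumour effect of day 5 itself, which leaves this count without a bearing on chance. The highest of the draws that mixed the day 5 groups called 537.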

How the results depend on the processing

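The settings without 2 day 5 tumour libraries that held gut or testis RNA, and without the 2 control libraries with the most salivary gland RNA (1531 and 1491 CPM of its markers, at most 262 in the other controls), were chosen only after the marker sums had been seen. Among named genes 3819 values kept their direction and side of the threshold, 102 lost their call and 21 gained one, and among lists 5805, 122 and 189. None of these was reversed. Of the lost gene calls 67 came from leaving out 1 library, and 76 of the lost list calls from an estimated correlation. Of all genes called at day 5, 1 was called in the opposite direction without replicate 1 of tumour day 5, and 1 without the 2 day 5 tumour libraries. DESeq2 gave no adjusted p for 46 genes, which were left out of its counts. A count of 3 corresponds to between 0.0855 and 0.234 CPM after TMM scaling, depending on the library, and levels below that rest on fewer counts.

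A minimum of 2-fold left 713, 2195, 1225, 1987, 1387, 768, 99, 2145 and 2350 genes, in the order in which the comparisons were described, since it counts fewer genes by construction. With only the 8 compared libraries in the model, the tumour effect at day 4 had 1065 genes in place of 2191, and day 11 against day 8 had 835 in place of 291. Day 8 against day 5 had 1193 genes in place of 2270 without the 2 day 5 tumour libraries, with fewer samples. Day 11 against day 8 had 187 genes with no low-count filter, 559 with DESeq2, and between 137 (without replicate 1 of day 8) and 277 (without replicate 4 of day 8) without 1 library. Beyond the fewer samples, the cause was not tested for any of these.

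With an estimated correlation the number of lists called fell to 0 from 6 (tumour effect at day 4), 10 (day 5), 3 (their difference), 12 (controls, day 5 against 4), 12 (tumours, day 5 against 4), 10 (day 11 against 8), 4 and 6 (days 8 and 11 against control day 5), and to 1 from 14 for day 8 against day 5. With no low-count filter it was 12 in place of 6 at day 4, 10 in place of 3 for the difference and 9 in place of 4 for day 8 against control day 5. The rank test gave 5 for the difference and 8 for day 8 against control day 5, and scaling without the 20 most abundant genes gave 10 at day 4. Without the 2 control libraries 7 lists were called for the difference. Leaving out 1 library gave 6 to 10 at day 4, 3 to 5 for the difference and 4 to 7 for day 8 against control day 5. With no low-count filter the tumour effects of days 4 and 5 had r = 0.215 and rho = 0.256 in place of 0.449 and 0.436, and the course of days 4 to 5 in controls and tumours r = 0.134 and rho = 0.233 in place of 0.367 and 0.421. The tumour effect at day 5 and the change from day 8 to day 11 then had r = -0.0823 in place of 0.041. The cause was not tested for any change of the list counts or of these correlations.

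No pairing of the libraries by replicate number was seen. Deviations of same-numbered libraries had a mean r of 0.021, against -0.00676 for other pairs, and 28.3% of 60 same-numbered pairs had an r over 0.1. For 6 of 24 libraries the mean r was highest with the libraries of their own number. With 4 numbers chance alone gives about that share. With the replicate number as a block 2105, 4689, 2445, 4700, 3768, 2233, 303, 4750 and 5023 genes were called, in the same order as above. The block raised the lists called for day 8 against control day 5 from 4 to 7. Among the values of named genes 3 lost their call and 1 gained one.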

Other observations

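The tests here follow the lists and contrasts fixed before, except the correlation of NimC2 with Fbp1, which was chosen after the group means of both genes had been seen. From day 4 to day 5 in tumour-bearing larvae several gene groups changed that the comparisons above did not name. Of 6 clock genes 4 rose and none fell (4 adjusted over the list alone), led by per at 3.60 ± 0.39, cyc at 0.95 ± 0.18 and tim at 0.88 ± 0.25. The list was called by camera (adjusted p = 0.0245; adjusted p = 0.15 with an estimated correlation). The lysosomal protease genes CtsB (1.60 ± 0.20) and CtsL1 (1.26 ± 0.24) and the autophagy gene Atg8a (1.00 ± 0.18) were among 9 of 24 members of the autophagy and lysosome list that rose, with 1 lower (9 and 1 adjusted over the list alone). That list had a camera adjusted p of 0.0235, with adjusted p = 0.651 with an estimated correlation and 0.059 without replicate 2 of tumour day 4. Basement membrane genes fell in 9 of 17 cases and rose in none (9 adjusted over the list alone), with the collagen IV chains vkg at -1.54 ± 0.21 and Col4a1 at -1.33 ± 0.18, and PH4alphaEFB at -1.58 ± 0.18. In the oxidative stress list 10 of 20 genes fell and 2 rose (11 and 2 adjusted over the list alone), with the glutathione S-transferase genes GstD1 at -2.03 ± 0.21 and GstE6 at -1.72 ± 0.32. Camera called both of these lists at adjusted p = 0.0235, with adjusted p = 0.483 and 0.15 with an estimated correlation and 0.0512 for both by the rank test.

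From day 5 to day 8 with tumours 10 of 20 oxidative stress genes fell and none rose (10 adjusted over the list alone), with Prx2 at -1.52 ± 0.29 (camera, adjusted p = 0.0207, and adjusted p = 0.184 with an estimated correlation). Of 24 genes of DNA replication and the cell cycle 4 rose and none fell (4 adjusted over the list alone), with the ribonucleotide reductase gene RnrS at 2.53 ± 0.28 and CycE at 1.11 ± 0.24 (camera, adjusted p = 0.00939, and adjusted p = 0.622 with an estimated correlation). Of 20 members of the ecdysone list 5 were called higher and 1 lower (5 and 1 adjusted over the list alone), with Eip78C at 4.09 ± 0.40 and Hr4 at 2.88 ± 0.46 (camera, adjusted p = 0.00228, and adjusted p = 0.184 with an estimated correlation). The RNAs roX1 and roX2, which males use in dosage compensation, summed to 55.6 ± 10.9, 217 ± 62.1, 385 ± 150 and 822 ± 97.2 CPM with tumours at days 4, 5, 8 and 11. In controls of days 4 and 5 they summed to 68.8 ± 12.98 and 221 ± 94.98 CPM, and the sex of the larvae is not given in the labels.

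NimC2, listed beforehand as a haemocyte marker, followed the storage protein receptor gene Fbp1 over the 6 groups. It was at 448 and 4115 CPM in controls of days 4 and 5, and at 5.37, 42.5, 315 and 153 CPM with tumours at days 4, 5, 8 and 11. A hypothesis is that both genes share a response in the fat body. Deviations from the group means across the 24 libraries had a Pearson r of 0.873 (permutation test within groups, 100000 resamples, p = 0.0022, adjusted p = 0.0022). Spearman's rho was 0.845 (same permutation test, p = 7e-04, adjusted p = 0.0014). The adjustment covers these 2 tests of the same pair of genes, not the choice of the pair after the group means were seen. Pearson's r was 0.81 without the 2 libraries farthest from the median of Fbp1. The value is consistent with a shared response, but NimC2 ranked only 19 of 8706 genes by its r with Fbp1. Other genes thus followed Fbp1 as closely, and a common state of the fat body in each pool is an equally open reading. NimC2 lay between 0.743% and 3.32% of the Fbp1 level in every library. Hml, another haemocyte marker, did not follow it, with 9.92 ± 2.57 CPM in controls of day 5 and 253 ± 48.7 at day 11 with tumours.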
